A study of Homo sapiens with 12 samples.

How the data were processed

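RNA was measured in 12 libraries of 2 human acute myeloid leukaemia cell lines, MOLM13 and MV411 (also written MV4-11). Both lines carry an internal tandem duplication in the receptor tyrosine kinase gene FLT3. Each line was treated with the solvent DMSO or with the kinase inhibitor SGI-7079 at 10 nM for 24 h, with 3 libraries in each of the 4 groups. Groups and replicate numbers were taken from the sample labels. The labels call the replicates separate samples of a group but do not state that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

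Per the labels' protocols, total RNA of an integrity number over 7.0 was selected on oligo(dT) beads, fragmented and copied into strand-marked libraries by the dUTP method, and sequenced in pairs of 150 bases on an Illumina NovaSeq instrument. Selection for poly(A) tails leaves RNAs without a tail, such as ribosomal RNA and most replication-dependent histone mRNA, at low and selection-dependent levels. Per the submitters' processing notes, the tools used were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, with the genome build hg38. The series' design text states that genes were counted with featureCounts and that DESeq2 was used with thresholds on the log2 fold change and the false discovery rate. Whether the counting used the strand, and how reads matching several genes were treated, is not given in the sources used here. Values of genes that overlap others or have near-identical copies are therefore uncertain.

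The deposited table holds raw counts per gene, per the file headers, with no normalization, for 36041 genes under Ensembl identifiers. It also holds FPKM, which the authors computed per gene and library, per the file headers. Of the identifiers, 35731 are in the GENCODE 44 annotation used here for gene positions and types, on the same genome build. The smallest number of counts of a gene summed over the libraries was 1. Each value column matched the label of 1 library, and no value column was left over. Total counts ranged from 52352252 to 61862017 per library. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 9.31 to 13.74), so that no pair was treated as 1 library.

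Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the filterByExpr filter at its minimum count of 10, which kept 21438 genes. A single model with 1 mean per cell line and treatment was fitted to the 12 libraries. Its contrasts were SGI-7079 against DMSO in each line, the difference of these effects (MV411 minus MOLM13), and MV411 DMSO against MOLM13 DMSO. P-values were adjusted by the Benjamini-Hochberg method over the genes tested. In the text, a gene rose or fell where its adjusted p was under 0.05, and was called where its absolute log2 fold change was also over 1. Fold changes are log2 values, and each rests on 3 libraries per group. The standard error (SE) given with them is the absolute log2 fold change divided by the square root of the test's F statistic. It approximates the standard error of the model. Abundances are given in CPM, with library sizes multiplied by the TMM factors. The FPKM values served only in an alternative test. The test was tried on simulated counts of the MOLM13 comparison over 20624 genes, with 50 genes planted at each fold. A gene was found where its adjusted p was under 0.05, without the fold threshold, and mean counts were over the 12 libraries. Far fewer genes changed in the simulation than in the data, so its shares do not carry over directly. Of planted genes with a mean of at least 100 counts, 62.1% were found at 1.5-fold, 82.4% at 2-fold, 94.1% at 3-fold and 96.2% at 4-fold. Over all planted genes the shares were 36%, 56%, 66% and 56%, and the 120 genes found were 107 of these, 8 of a further 20 planted together as a list at 1.5-fold, and 5 false ones.

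Gene lists (31) for signalling, metabolism, cell cycle, myeloid differentiation and other cell types were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The test compares a list with the other genes. P-values were adjusted over the lists with at least 5 measured genes in a contrast, and a list was called at an adjusted p under 0.05. The test was repeated with an estimated correlation. Members were counted by their adjusted p over all genes, and again with the p adjusted over the list alone. The design, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. That rule took, in each line, the 10 called genes with the largest change in each direction that had at least 5 CPM in the higher group, no overlap between treated and control libraries, and a gene symbol. Antisense genes, pseudogenes and clone names were left out. It further took the members of each list with the smallest adjusted p, 6 genes per direction for the difference and 5 per direction for the baseline, and a fixed set of genes around FLT3 signalling and apoptosis. Other genes are named as chosen after their values were seen. Where a group had 0 counts in its 3 libraries, a fold was computed against a floor of 3 counts over the group and is given as a lower bound, which covers counting error only.

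The alternatives were DESeq2 1.42.0, another size factor (RLE), no filter on low counts, each line fitted alone, the replicate number as a block, other fold thresholds (none, or glmTreat), limma on log2 FPKM with a pseudocount of 1 or 0.1, fry for the lists, and each library left out in turn. An enrichment test of KEGG terms was added after the data were seen. Its background was the 6207 tested genes with a term.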

Results

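RNA sequencing compared DMSO and SGI-7079 in MOLM13 and MV411, leukaemia lines of the monocytic lineage that depend on mutant FLT3. SGI-7079 is a small-molecule kinase inhibitor known as an inhibitor of the receptor AXL, and the study asked how it acts on transcription in FLT3-mutant cells. The 12 libraries held 52352252 to 61862017 counts, with group means of 59086846 ± 1281613 (SD, n = 3) in MOLM13 DMSO, 57700425 ± 2915112 in MOLM13 SGI-7079, 59607302 ± 2266924 in MV411 DMSO and 56795900 ± 4312215 in MV411 SGI-7079. The first principal component held 70.6% of the variance and separated the lines, and the second held 18.1% and separated treated from control libraries in both lines. Treated libraries held more genes with at least 10 counts, at 19124 ± 224 (SD, n = 3) against 18145 ± 49.0 in MOLM13 and 20069 ± 173 against 18907 ± 70.8 in MV411. The share of mitochondrial ribosomal RNA was also higher in treated libraries, at 0.94% ± 0.02 against 0.534% ± 0.015 in MOLM13 and 0.837% ± 0.027 against 0.406% ± 0.007 in MV411 (SD, n = 3).

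In MOLM13, SGI-7079 lowered genes of cell division and of amino acid supply. FLT3 itself rose, as did 16 of 26 monocyte marker genes, while 4 of those markers fell. FLT3 (ENSG00000122025, chromosome 13, 28003274 to 28100592, hg38) rose by 0.94 ± 0.02 in log2 (SE, n = 3 per group; adjusted p = 7.4e-12), from 327 to 625 CPM. AXL, a receptor tyrosine kinase of the TAM family (ENSG00000167601, chromosome 19, 41219223 to 41261766), rose by 1.54 ± 0.09 (adjusted p = 1.53e-08). PLK1, a mitotic kinase, changed by -2.13 ± 0.04 (adjusted p = 6e-13), and PHGDH, the entry enzyme of serine synthesis, by -1.86 ± 0.09 (adjusted p = 9.54e-10). CSF1R, the receptor for the macrophage growth factor M-CSF, rose 5.42-fold. At the called threshold 1917 genes were higher and 738 lower of 21438 tested, and by adjusted p alone 4971 rose and 5052 fell. The excess of higher calls lay among genes of low abundance, with 409 higher and 418 lower among genes of at least 5 CPM on average and 1508 and 320 below that. Of protein-coding genes 958 were called higher and 624 lower, and of long non-coding RNAs 719 and 61.

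Among genes of at least 5 CPM in the higher group and without overlap between groups, the largest called increases in MOLM13 were in the histone gene H2AC6 (3.86 ± 0.21), the peptidase gene DPEP2 (3.62 ± 0.14), TRIM73 (3.51 ± 0.25), the matrix gene TNXB (3.46 ± 0.37), the complement protease gene MASP2 (3.39 ± 0.77), the B-cell adaptor gene BLNK (3.37 ± 0.60) and ADAM28 (3.28 ± 0.21), followed by LINC01226, PTGDS and CFAP70 at 3.08, 3.03 and 3.02. The largest decreases were in STON1 (-3.96 ± 0.28), IGFBP2, a binding protein of insulin-like growth factors (-3.89 ± 0.12), TNFRSF19 (-3.62 ± 0.50), INHBA, a subunit of activin (-3.20 ± 0.16), ADM2 (-2.79 ± 0.30), CKAP4 (-2.73 ± 0.20), the cell-cycle factor E2F8 (-2.57 ± 0.09) and CHAC1, a glutathione-degrading enzyme (-2.54 ± 0.18), with TUBA8 and UNCX at -2.38 and -2.27. TRIM73, TNXB and H2AC6 have near-identical copies in the genome, so that the counting of shared reads makes their values uncertain. MASP2 was uneven, at 6.07, 8.30 and 0.83 CPM in MOLM13 SGI-7079 replicates 1 to 3, against 0.42 to 0.60 CPM in MOLM13 DMSO.

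In MV411, the decreases in cell division genes were deeper and the antigen presentation genes rose. PIM1, a kinase gene induced by STAT5 (ENSG00000137193, chromosome 6, 37170152 to 37175428), changed by -2.48 ± 0.08 (SE, n = 3 per group; adjusted p = 1.26e-11), from 91.8 to 16.4 CPM. MCM10, a replication initiation factor, changed by -3.45 ± 0.05 (adjusted p = 2.07e-14), and ETV4, a transcription factor induced by ERK signalling, by -4.09 ± 0.26 (adjusted p = 1.26e-08). HLA-DRA, a chain of the MHC class II complex, rose 4.3-fold, from 41.2 to 177 CPM (adjusted p = 1.07e-09), and FLT3 rose by 0.36 ± 0.02 (adjusted p = 1.78e-08), from 385 to 494 CPM. The called genes were 2367 higher and 1304 lower, and by adjusted p alone 5830 rose and 5205 fell. Among genes of at least 5 CPM 689 were called higher and 826 lower, and below that 1678 and 478. Of protein-coding genes 1327 were higher and 1044 lower, and of long non-coding RNAs 763 and 147. The median log2 fold change over all tested genes was 0.114 in MV411 and 0.054 in MOLM13. Without any 1 of 9 libraries, the 6 of MOLM13, MV411 DMSO replicates 1 and 2 and MV411 SGI-7079 replicate 1, the MV411 median was 0.03 to 0.056.

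Under the same conditions, the largest increases in MV411 were in IGF1, a growth factor gene (5.66 ± 0.40), LILRB3, an inhibitory receptor of myeloid cells (4.71 ± 0.36), MROH7-TTC4 (4.43 ± 1.05), TMEM86A (4.35 ± 0.62), the creatine kinase gene CKB (4.20 ± 0.21), H2AC6 (3.90 ± 0.20), SLC26A11 (3.87 ± 0.42) and MYOM1 (3.76 ± 0.20), with the lysosomal nuclease gene DNASE2 and the Fc receptor gene FCGR2C at 3.74 and 3.73. After ETV4, the largest decreases were in the neuropeptide gene GAL (-4.01 ± 0.27), GLB1L2 (-3.63 ± 0.35), MCM10, the replication genes CDC6 (-3.29 ± 0.05) and CDC45 (-3.29 ± 0.09), the cell-cycle factor MYBL2 (-3.28 ± 0.07), the kinetochore gene SPC25 (-3.25 ± 0.14), PHGDH (-3.16 ± 0.10) and DSCC1 (-3.12 ± 0.10). LILRB3 and FCGR2C have near-identical neighbours and MROH7-TTC4 is a read-through of overlapping genes, so their values are uncertain. MROH7-TTC4 stood at 5.74 without MV411 DMSO replicate 1 and at 3.77 without MV411 DMSO replicate 2.

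**Figure D1:**
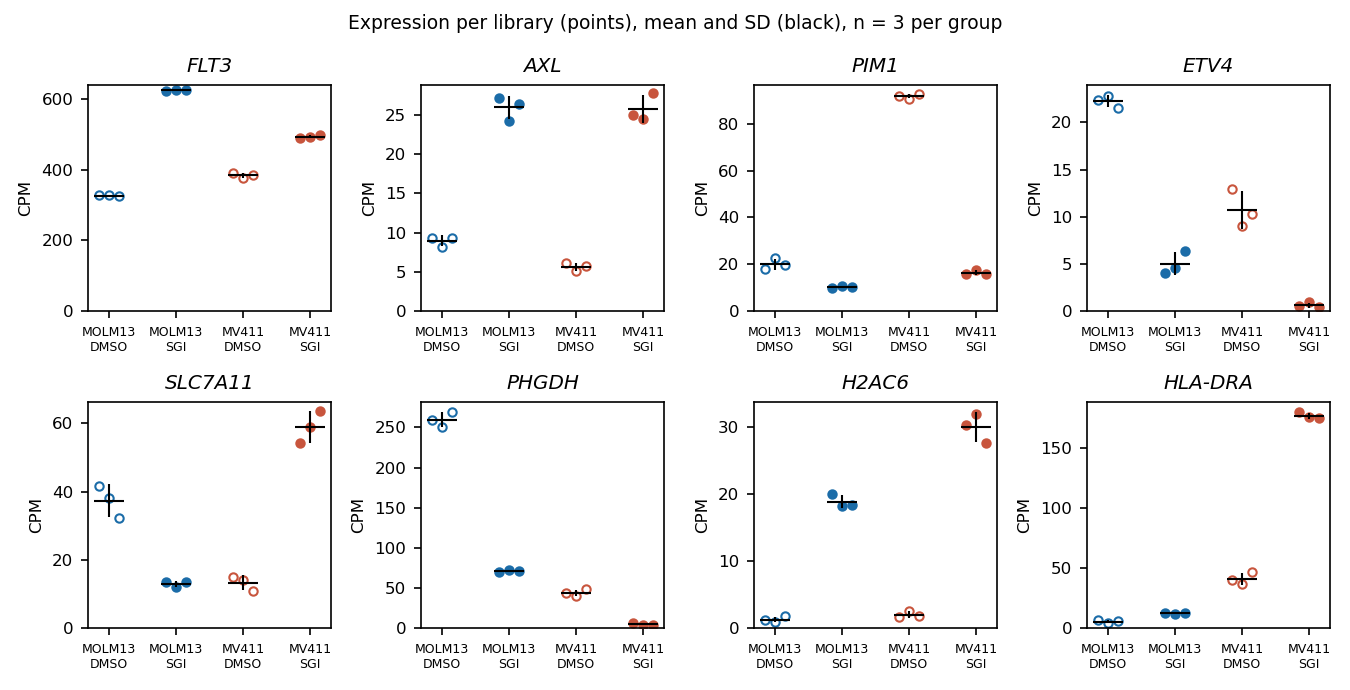
Expression in CPM (vertical axes, from 0) of 8 genes in the 4 groups, with 1 point per library and the mean and SD in black (n = 3 per group). FLT3 and AXL were higher in treated libraries of both lines, and SLC7A11 went from 37.4 to 13.0 CPM in MOLM13 and from 13.3 to 58.9 CPM in MV411.

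Genes downstream of FLT3 were examined by signalling branch. Of 18 measured targets of STAT5, the transcription factor activated by mutant FLT3, 0 rose and 13 fell in MOLM13 (median -0.41), and 1 rose and 13 fell in MV411 (median -0.74). The counts adjusted over the list alone were the same. CISH, a feedback inhibitor of cytokine signalling, changed by -1.23 ± 0.06 and -1.70 ± 0.06 in MOLM13 and MV411, CCND3, a G1 cyclin, by -0.93 ± 0.05 and -1.26 ± 0.05, and PIM1 by -0.96 ± 0.08 in MOLM13. SOCS2 fell by 0.69 ± 0.05 in MV411 and stood at -0.10 ± 0.05 in MOLM13 (adjusted p = 0.11). The list was called lower in both lines (adjusted p = 2.34e-04 and 2.14e-05), with adjusted p = 0.0733 and 0.0743 with an estimated correlation. IL2RA had 0 counts in both MOLM13 groups and so no fold, and without it the MOLM13 median was -0.42. Of 19 targets of ERK signalling and its feedback, 2 rose and 10 fell in MOLM13 (median -0.62), and 2 rose and 12 fell in MV411 (median -1.28), or 2 and 10, and 2 and 13, adjusted over the list alone. DUSP6, an ERK phosphatase, changed by -0.47 ± 0.08 and -1.47 ± 0.08, SPRY4, an inhibitor of receptor signalling, by -1.12 ± 0.18 and -1.50 ± 0.22, and ETV4 by -2.15 ± 0.22 in MOLM13. FOS, an immediate early gene, rose by 1.54 ± 0.11 in MOLM13 and stood at -0.08 ± 0.11 in MV411 (adjusted p = 0.551), or at -0.28 without MV411 SGI-7079 replicate 1 (adjusted p = 0.0364). ERK targets were called lower (adjusted p = 0.0235 and 2.68e-04), with adjusted p = 0.142 and 0.0584 with an estimated correlation.

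Of 20 targets of FOXO, the transcription factors that AKT holds outside the nucleus, 12 rose and 1 fell in MOLM13 (median 0.33), and 11 rose and 4 fell in MV411 (median 0.30), with the same counts adjusted over the list alone. BCL6, a transcriptional repressor, rose by 1.48 ± 0.17 and 1.93 ± 0.17, PIK3IP1, an inhibitor of PI3-kinase, by 1.94 ± 0.11 and 1.56 ± 0.11, and TXNIP, a regulator of glucose uptake, by 1.31 ± 0.04 and 1.21 ± 0.04. CDKN1B, the cell-cycle inhibitor p27, fell by 0.25 ± 0.04 in MOLM13 and rose by 0.10 ± 0.04 in MV411 (adjusted p = 0.0468), with a difference of 0.35 (adjusted p = 6.86e-04). The MV411 rise was lost without any 1 of 11 libraries, the 6 of MOLM13, the 3 of MV411 DMSO and MV411 SGI-7079 replicates 1 and 2 (0.02 to 0.11, adjusted p 0.0698 to 0.814). FOXO targets were called higher (adjusted p = 9.31e-04 in MOLM13 and 0.0413 in MV411), with adjusted p = 0.042 and 0.142 with an estimated correlation. In MV411 the call was lost without any 1 of 9 libraries, the 6 of MOLM13, MV411 DMSO replicate 1 and MV411 SGI-7079 replicates 1 and 2 (adjusted p 0.0509 to 0.0638). Of 7 measured kinases and ligands tied to the compound, 2 rose and 2 fell in MOLM13 (median 0.23) and 3 rose and 2 fell in MV411 (median 0.14), with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.577 and 0.826). AXL rose by 2.19 ± 0.10 in MV411. GAS6, the ligand of AXL, changed by -0.24 ± 0.03 in MOLM13 and by -1.46 ± 0.04 in MV411. MERTK, another TAM receptor, rose by 2.34 ± 0.66 in MV411 (adjusted p = 0.00837) and stood at 1.36 ± 1.06 in MOLM13 at 0.0302 and 0.0798 CPM (adjusted p = 0.326), and rose without MOLM13 DMSO replicate 2, when MOLM13 DMSO had 0 counts (adjusted p = 0.0269, at least 1.59 in log2). TYRO3 changed by -1.21 ± 0.18 and -1.01 ± 0.18. Without MV411 SGI-7079 replicate 1 or 3 the MV411 value of TYRO3 was -0.96, inside the fold threshold.

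Genes of the cell cycle fell in both lines. Of 30 DNA replication genes, 30 fell in MOLM13 (median -1.16) and 30 in MV411 (median -2.42), also adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, went from 318 to 79.6 CPM in MOLM13 and changed by -3.04 ± 0.05 in MV411, and MCM4 and MCM6, subunits of the replicative helicase, by -1.20 ± 0.03 and -1.05 ± 0.03 in MOLM13 and -2.61 ± 0.03 and -2.38 ± 0.03 in MV411. Of 24 mitosis genes, 24 fell in MOLM13 (median -1.77) and 24 in MV411 (median -2.22), also adjusted over the list alone. They included PLK1 (-2.33 ± 0.04 in MV411), BUB1, a spindle checkpoint kinase (-1.93 ± 0.04 and -2.34 ± 0.04), and TPX2, a spindle assembly factor (-1.65 ± 0.04 and -2.20 ± 0.04). Both lists were called lower, replication with adjusted p = 1.37e-24 and 2.35e-28 and mitosis with adjusted p = 9.14e-24 and 2.87e-22, and with an estimated correlation both calls held.

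The replication-dependent histone genes, whose transcripts mostly end without a poly(A) tail, went the other way. Of 11 measured, 7 rose and 0 fell in MOLM13 (median 2.01), and 6 rose and 0 fell in MV411 (median 1.63), or 6 and 1 in MV411 adjusted over the list alone. H2BC9 and H3C8 had 0 counts in both MOLM13 groups and so no fold. Without them, and with H2AC8, at 0 counts in 1 group, at its bound, the MOLM13 median was also 2.01, over 9 members. H2AC6 (ENSG00000180573, chromosome 6, 26124145 to 26139116) rose from 1.3 to 18.9 CPM in MOLM13 and from 2.01 to 30.0 CPM in MV411, and H2BC5 rose by 3.39 ± 0.34 and 3.22 ± 0.33. These histone genes were called in MOLM13 (adjusted p = 0.0189, and adjusted p = 0.0629 with an estimated correlation) and not in MV411 (adjusted p = 0.128). In MOLM13 the call was lost without MOLM13 SGI-7079 replicate 3 or MV411 DMSO replicate 2 (adjusted p 0.0503 to 0.0598). Of 60 other genes of RNAs without a tail (snoRNA, scaRNA, 7SK and 7SL), 1 rose and 2 fell in MOLM13 (median -0.32), and 2 rose and 14 fell in MV411 (median -0.67). RN7SK, 1 of the 60 and chosen after its values were seen, rose by 1.249 ± 0.331 and 1.32 ± 0.33. The mitochondrial ribosomal RNA MT-RNR1, which carries a short oligo(A) tail and was also chosen afterwards, rose by 1.22 ± 0.06 and 1.51 ± 0.06. Histone copies share reads, which makes single members uncertain.

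Lists for growth and biosynthesis were lower. Of 25 ribosome biogenesis genes, 0 rose and 23 fell in MOLM13 (median -0.56), and 1 rose and 24 fell in MV411 (median -0.95). NOP56, a nucleolar protein, changed by -0.67 ± 0.03 and -1.19 ± 0.03, and MRTO4 by -0.75 ± 0.04 and -1.49 ± 0.04. Of 19 metabolic targets of MYC, 0 rose and 18 fell in each line (medians -0.64 and -1.13), among them PAICS, a purine synthesis enzyme (-0.79 ± 0.04 and -1.66 ± 0.04), and HSPD1, a mitochondrial chaperone (-0.98 ± 0.02 and -1.13 ± 0.02). MYC itself changed by -0.19 ± 0.03 in MOLM13 and -0.77 ± 0.03 in MV411. Counts adjusted over the list alone were the same for both lists. Ribosome biogenesis was called with adjusted p = 1.06e-14 and 1.22e-15 and the MYC targets with adjusted p = 1.76e-13 and 6.21e-15, and the 4 calls held with an estimated correlation. Of 30 ribosomal protein genes, by contrast, 28 rose in MOLM13 and 23 in MV411, with 0 falling and the same counts adjusted over the list alone (medians 0.28 and 0.18). RPL13 rose by 0.48 ± 0.03 and 0.28 ± 0.03. Ribosomal proteins were called higher (adjusted p = 8.76e-12 and 1.66e-05), with adjusted p = 0.195 and 0.376 with an estimated correlation.

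Lists of amino acid metabolism were called lower in both lines. Of 26 targets of ATF4, the transcription factor of the amino acid response, 0 rose and 22 fell in MOLM13 (median -0.94), and 4 rose and 15 fell in MV411 (median -0.47). The counts adjusted over the list alone were 0 and 22, and 4 and 16. PSAT1, the next enzyme of serine synthesis, changed by -1.75 ± 0.05 and -2.21 ± 0.05, and SLC7A5, a transporter of large neutral amino acids, by -1.46 ± 0.05 and -1.51 ± 0.05. SLC7A11, the cystine transporter (ENSG00000151012, chromosome 4, 138164097 to 138242349), changed by -1.52 ± 0.12 in MOLM13 and rose by 2.15 ± 0.12 in MV411. The list was called (adjusted p = 2.47e-13 and 2.05e-05), and in MV411 had adjusted p = 0.088 with an estimated correlation. Of 20 tRNA synthetases, 1 rose and 19 fell in MOLM13 (median -0.69) and 1 rose and 17 fell in MV411 (median -0.51), the same as adjusted over the list alone. GARS1, for glycine, changed by -1.32 ± 0.04 in MOLM13 and went from 183 to 91.7 CPM in MV411, and MARS1, for methionine, by -1.13 ± 0.03 and -0.56 ± 0.03. The synthetases were called in both lines (adjusted p = 3.85e-13 and 9.16e-09), also with an estimated correlation.

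Lists of energy metabolism were called lower, except mitochondrially encoded mRNAs in MOLM13. Of 22 glycolysis genes, 4 rose and 16 fell in MOLM13 and 3 rose and 16 fell in MV411 (medians -0.40 and -0.58). LDHA, lactate dehydrogenase, changed by -1.08 ± 0.04 and -1.55 ± 0.04, and ENO1, the enolase, by -0.58 ± 0.04 and -0.95 ± 0.04. The calls (adjusted p = 6.61e-06 and 1.66e-05) had adjusted p = 0.154 and 0.155 with an estimated correlation. Of 28 oxidative phosphorylation genes, 1 rose and 27 fell in MOLM13 and 1 rose and 25 fell in MV411 (medians -0.43 and -0.54), with ATP5MC1, an ATP synthase subunit, at -0.77 ± 0.06 and -1.19 ± 0.06. This list was called (adjusted p = 8.76e-12 and 3.98e-10), in MV411 with adjusted p = 0.0645 with an estimated correlation. Of 13 mitochondrially encoded mRNAs, 2 rose and 8 fell in MOLM13 (median -0.17, adjusted p = 0.0767) and 13 fell in MV411 (median -0.53, adjusted p = 1.51e-07, and adjusted p = 0.132 with an estimated correlation). MT-CO2, a cytochrome oxidase subunit, changed by -0.28 ± 0.04 and -0.82 ± 0.04. Without MV411 SGI-7079 replicate 2 the MOLM13 list had adjusted p = 0.0488. Counts adjusted over the list alone were the same for these 3 lists.

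Of 12 fatty acid synthesis genes, 2 rose and 9 fell in MOLM13 and 3 rose and 9 fell in MV411 (medians -0.53 and -0.57), with FADS2, a desaturase, at -1.17 ± 0.05 and -1.34 ± 0.05 and FASN, fatty acid synthase, at -0.60 ± 0.04 and -1.07 ± 0.04. The calls (adjusted p = 5.09e-04 and 0.00681) had adjusted p = 0.072 and 0.138 with an estimated correlation. Of 24 cholesterol synthesis genes, 5 rose and 8 fell in MOLM13, where the median was 0.03, the mean -0.02 and the test pointed down without a call (adjusted p = 0.643). In MV411 4 rose and 13 fell (median -0.31), called with adjusted p = 0.00193 and adjusted p = 0.138 with an estimated correlation. SQLE, squalene epoxidase, fell by 0.83 ± 0.04 in MV411 and stood at 0.06 ± 0.04 in MOLM13 (adjusted p = 0.298). Counts adjusted over the list alone were the same for both lipid lists.

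**Figure D2:**
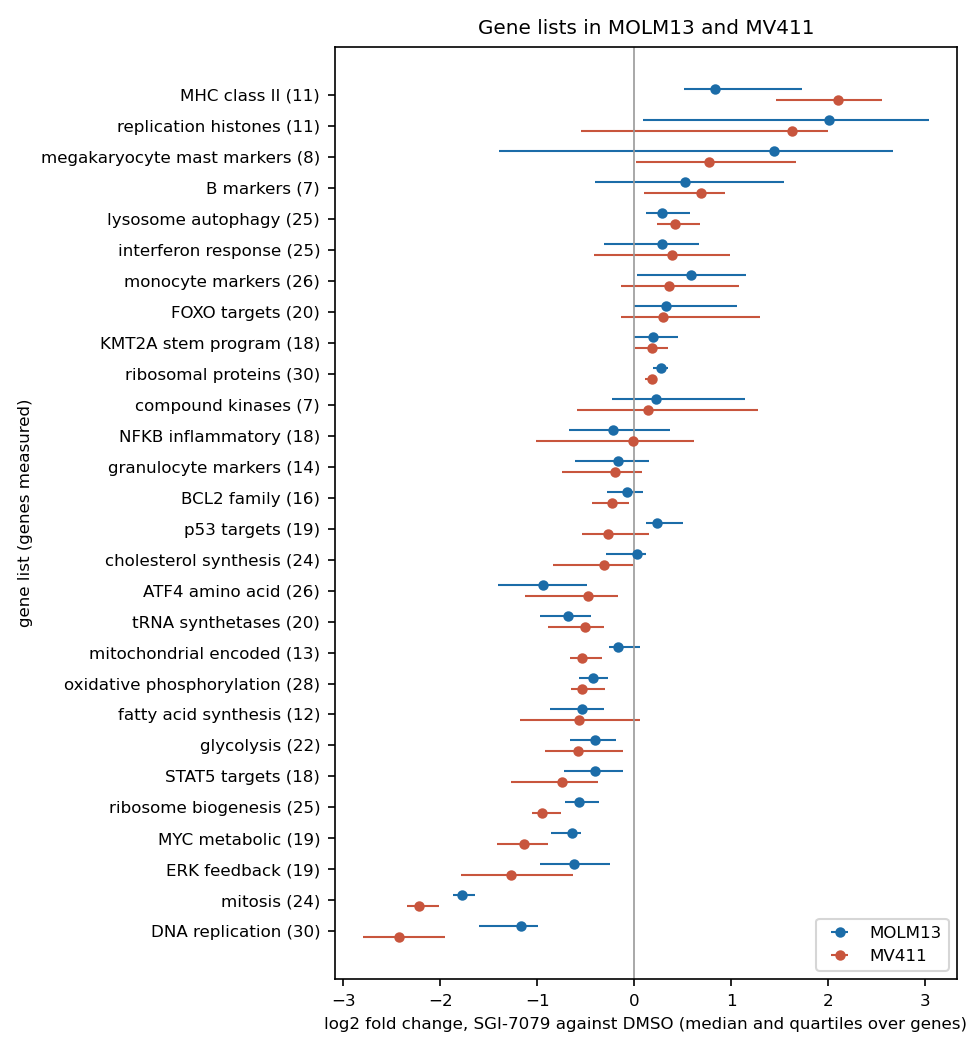
Median and quartiles over genes of the log2 fold change of SGI-7079 against DMSO (horizontal axis) in 28 gene lists with their number of measured genes (vertical axis), for MOLM13 (blue) and MV411 (red). DNA replication had medians of -1.16 and -2.42 and MHC class II of 0.84 and 2.103, and the bars are spreads over genes, not errors between replicates.

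The monocyte, MHC class II and lysosome lists were called higher in both lines. Of 26 monocyte markers, 16 rose and 4 fell in MOLM13 (median 0.58) and 12 rose and 6 fell in MV411 (median 0.36), the same as adjusted over the list alone. ITGAX, the integrin CD11c, rose by 2.11 ± 0.06 and 2.56 ± 0.06, and CSF1R by 2.44 ± 0.06 and 1.44 ± 0.05. The list was called (adjusted p = 3.78e-04 and 0.0467), in MV411 with adjusted p = 0.134 with an estimated correlation. That MV411 call was lost without any 1 of 10 libraries, the 6 of MOLM13, MV411 DMSO replicates 1 and 2 and MV411 SGI-7079 replicates 1 and 3 (adjusted p 0.0607 to 0.0795). Of 11 MHC class II genes, 7 rose and 0 fell in MOLM13 (median 0.84, or 1.01 without HLA-DRB5, which had 0 counts in both groups and no fold) and 11 rose in MV411 (median 2.103), the same as adjusted over the list alone. CIITA, the master activator of the class (ENSG00000179583, chromosome 16, 10866222 to 10943021), rose by 0.84 ± 0.07 and 1.67 ± 0.06, and HLA-DRA by 1.18 ± 0.12 in MOLM13. The calls (adjusted p = 5.72e-04 and 3.23e-06) held with an estimated correlation. HLA genes share reads, so single members are uncertain. Of 25 lysosome and autophagy genes, 20 rose and 2 fell in MOLM13 and 19 rose and 4 fell in MV411 (medians 0.29 and 0.42), the same as adjusted over the list alone. CTSD, a cathepsin, rose by 0.58 ± 0.03 and 0.94 ± 0.03. Lysosome genes were called (adjusted p = 2.32e-06 and 2.09e-05). With an estimated correlation the MOLM13 call held, at adjusted p = 0.05 after rounding and just under the threshold before it, and MV411 had adjusted p = 0.0858.

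Of 14 granulocyte markers, 2 rose and 7 fell in MOLM13 (median -0.16, or -0.30 without CAMP, which had 0 counts in both groups and no fold) and 3 rose and 6 fell in MV411 (median -0.20), or 3 and 7 in each line adjusted over the list alone, without a call (adjusted p = 0.0944 and 0.146). CSF3R, the receptor for the granulocyte growth factor G-CSF, rose by 1.48 ± 0.04 and 1.28 ± 0.04, and the granule protease gene PRTN3 changed by -0.66 ± 0.04 and -1.34 ± 0.04. Of 18 genes of the stem cell program driven by KMT2A fusions, 9 rose and 4 fell in MOLM13 and 9 rose and 3 fell in MV411 (medians 0.20 and 0.18), the same as adjusted over the list alone. RUNX2, a transcription factor, rose by 0.99 ± 0.03 and 0.56 ± 0.03. The calls (adjusted p = 0.0196 and 0.0413) had adjusted p = 0.117 and 0.143 with an estimated correlation. That in MV411 was lost without any 1 of 10 libraries, the 6 of MOLM13, the 3 of MV411 DMSO and MV411 SGI-7079 replicate 1 (adjusted p 0.0602 to 0.134).

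Targets of p53 moved apart in the lines. Of 19, 11 rose and 2 fell in MOLM13 (median 0.24), or 14 and 2 adjusted over the list alone, and 4 rose and 11 fell in MV411 (median -0.27), the same as adjusted over the list alone. TP53INP1 rose by 1.85 ± 0.08 and 1.18 ± 0.08, CDKN1A, the cell-cycle inhibitor p21, changed by -0.37 ± 0.06 and -1.07 ± 0.06, and AEN, a nuclease, by -0.32 ± 0.05 and -1.20 ± 0.05. The list was called higher in MOLM13 (adjusted p = 7.58e-04, also with an estimated correlation) and lower in MV411 (adjusted p = 0.03, and adjusted p = 0.0858 with an estimated correlation). Of 16 genes of the BCL2 family of apoptosis regulators, 2 rose and 5 fell in MOLM13 and 2 rose and 7 fell in MV411 (medians -0.07 and -0.23), the same as adjusted over the list alone, without a call (adjusted p = 0.662 and 0.0651). The MOLM13 mean was 0.03, against a negative median and a test pointing down. BMF, a pro-apoptotic member, rose by 2.66 ± 0.06 and 1.69 ± 0.05. The anti-apoptotic MCL1 changed by -0.27 ± 0.03 and -0.33 ± 0.03, and BCL2 and the pro-apoptotic BCL2L11 changed in MV411 by -0.37 ± 0.04 and -0.22 ± 0.05 and stood at 0.03 ± 0.04 and 0.01 ± 0.05 in MOLM13 (adjusted p = 0.58 and 0.891). In MV411 the list was called without any 1 of 8 libraries, the 6 of MOLM13, MV411 DMSO replicate 2 and MV411 SGI-7079 replicate 1 (adjusted p 0.0285 to 0.0466).

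Of 25 interferon response genes, 8 rose and 3 fell in MOLM13 and 13 rose and 4 fell in MV411 (medians 0.28 and 0.39), the same as adjusted over the list alone, without a call (adjusted p = 0.439 and 0.0688). RSAD2, an antiviral enzyme, rose by 1.48 ± 0.17 and 1.99 ± 0.17, while the chemokine gene CXCL10 changed by -1.32 ± 0.10 and -1.23 ± 0.12. Without MOLM13 SGI-7079 replicate 1, MV411 DMSO replicate 1 or MV411 SGI-7079 replicate 1 the MV411 list was called (adjusted p 0.0318 to 0.0494). Of 18 inflammatory targets of NF-kappaB, 7 rose and 7 fell in each line (medians -0.22 and -0.01), or 8 and 7 in MV411 adjusted over the list alone. The means were -0.19 and -0.26 while the test pointed up without a call (adjusted p = 0.971 and 0.846). TNF, an inflammatory cytokine, changed by -1.25 ± 0.06 and -1.93 ± 0.07, and NFKB2 rose by 0.40 ± 0.04 and 0.73 ± 0.04.

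Of 7 B-cell markers 2 rose and 1 fell in MOLM13 (median 0.53, or 0.93 without BLK, at 0 counts in both groups, and with IGHM, at 0 counts in 1 group, at its bound) and 2 rose and 0 fell in MV411 (median 0.69), and of 8 megakaryocyte and mast cell markers 3 rose and 1 fell, and 3 rose and 0 fell (medians 1.45 and 0.77). Neither list was called (adjusted p = 0.502 and 0.404 for B cells, 0.577 and 0.416 for the other). Adjusted over the list alone the counts were the same, except for 2 lower in the megakaryocyte list in MOLM13. KIT, a receptor of mast cells and progenitors, rose by 1.73 ± 0.19 and 2.41 ± 0.18. Only 4 T and NK cell markers, 2 erythroid markers and 4 stromal or epithelial markers were measured, too few for the test. Of these, NKG7 rose by 0.43 ± 0.08 and 0.32 ± 0.08, the erythropoietin receptor gene EPOR changed by -0.26 ± 0.10 and -0.56 ± 0.10 in MOLM13 and MV411, and the keratin gene KRT8 rose from 2.59 to 4.89 CPM in MOLM13 and from 2.27 to 6.41 CPM in MV411. The MV411 rise of NKG7 was lost without MV411 DMSO replicate 1 or 2 or MV411 SGI-7079 replicate 1 (adjusted p 0.0546 to 0.0623). The MOLM13 fall of EPOR was lost without MOLM13 DMSO replicate 1 or 3, MOLM13 SGI-7079 replicate 1, 2 or 3 or MV411 SGI-7079 replicate 1 (adjusted p 0.0549 to 0.16). In total 1 T and NK marker rose and 1 fell in each line, 0 erythroid markers rose and 1 fell in each line, and 2 stromal or epithelial markers rose in each line with 1 falling in MOLM13. Adjusted over the list alone, 2 of the T and NK markers were lower in MOLM13 and 2 higher in MV411, with the other counts the same.

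The responses of the lines were compared with each other, without shared control libraries. H2AC6, BMF and ITGAX were called higher and PLK1, RRM2, PHGDH and ETV4 lower in both lines. In all, 1113 genes were called higher in both, against 211.7 for independent lists of these sizes, and 476 were called lower in both, against 44.9. Opposite calls were 17, against 198.1, with 9 without MOLM13 SGI-7079 replicate 2 and 5 with each line fitted alone. SLC7A11 was among the opposite calls. The numbers for independent lists treat all tested genes alike, while higher calls lay mostly under 5 CPM (1508 in MOLM13 and 1678 in MV411). For such genes, background reads and weaker poly(A) selection in treated libraries stay open, as set out below. Of 4720 genes called in either line, 89.6% had the same direction. Across the 11224 genes of at least 5 CPM on average, the fold changes of the lines correlated with Pearson's r of 0.772 and Spearman's rho of 0.824, and across all tested genes with 0.483 and 0.646. These correlations are across genes, which are not independent replicates.

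**Figure D3:**
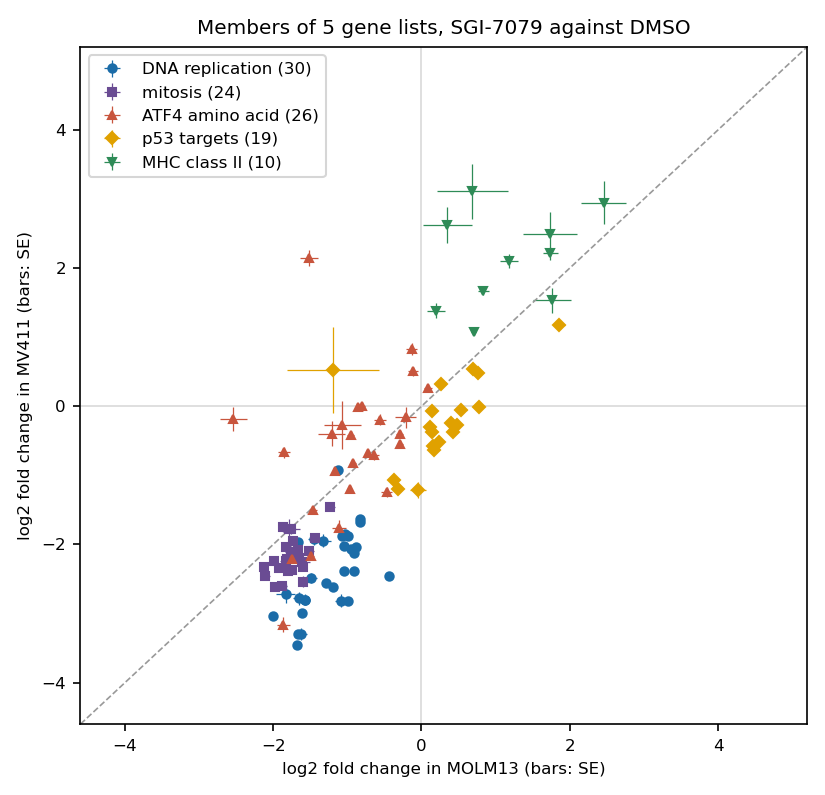
Log2 fold change of SGI-7079 against DMSO in MOLM13 (horizontal axis) and MV411 (vertical axis) for the members of 5 gene lists, with SE bars and the line of equal change dashed. Of 30 DNA replication genes 29 fell further in MV411 by the test of the difference, and 15 of 19 p53 targets were lower there relative to MOLM13.

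The difference of the effects was tested directly. Replication genes fell further in MV411, with MCM10 at -1.77 ± 0.07 (SE, n = 3 per group; adjusted p = 2.29e-09), MCM6 at -1.33 ± 0.04 (adjusted p = 8.27e-10) and MCM4 at -1.41 ± 0.05 (adjusted p = 1.05e-09) in MV411 minus MOLM13. Other genes lower in MV411 relative to MOLM13 were CSPG4, a surface proteoglycan (-1.99 ± 0.06), TCF19 (-1.54 ± 0.05) and the nucleoside transporter gene SLC29A1 (-1.62 ± 0.06). On the other side stood SLC7A11 (3.67 ± 0.17, adjusted p = 1.97e-08), PRAM1, a myeloid adaptor (2.12 ± 0.11), ZC3H3 (1.57 ± 0.06), the calcium channel gene CACNA2D4 (1.51 ± 0.05), TENT5A (1.19 ± 0.06) and LRG1 (1.09 ± 0.06). Without MOLM13 DMSO replicate 3 or MOLM13 SGI-7079 replicate 2, LRG1 stood at 0.98 to 1.00 and was not called. FLT3 rose less in MV411 (-0.57 ± 0.03, adjusted p = 1.27e-07), and PIM1 fell further there (-1.52 ± 0.11, adjusted p = 8.21e-07). At the called threshold 385 genes were higher and 387 lower in the difference, and by adjusted p alone 1898 and 2530.

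Among lists, the difference was negative for DNA replication (median -1.15, 1 higher and 29 lower of 30), mitosis (-0.41, 0 and 17 of 24, or 0 and 21 adjusted over the list alone), ribosome biogenesis (-0.40, 2 and 21 of 25), MYC targets (-0.46, 1 and 15 of 19), cholesterol synthesis (-0.40, 1 and 18 of 24) and p53 targets (-0.67, 0 and 15 of 19, or 0 and 16 adjusted over the list alone). For replication, mitosis and p53 targets adjusted p = 5.36e-04 with an estimated correlation, and the other 3 calls also held with it. MHC class II genes had a positive difference (median 0.84, 7 and 0 of 11, adjusted p = 9.11e-06), which held too. STAT5 targets (-0.34), ERK targets (-0.69), the BCL2 family (-0.25), ribosomal proteins (-0.12), mitochondrial mRNAs (-0.47), interferon response (0.21), ATF4 targets (0.14) and tRNA synthetases (0.09) were called, with adjusted p = 0.186, 0.0562, 0.2, 0.52, 0.0744, 0.0915, 0.363 and 0.27 with an estimated correlation. The ATF4 call was lost without MOLM13 DMSO replicate 1, MV411 DMSO replicate 2 or MV411 SGI-7079 replicate 1 (adjusted p 0.0591 to 0.0839). The call of tRNA synthetases was lost without any 1 of 9 libraries, the 6 of MOLM13, MV411 DMSO replicates 1 and 2 and MV411 SGI-7079 replicate 1 (adjusted p 0.134 to 0.265). Without the same 9 libraries in turn, glycolysis (adjusted p 0.0042 to 0.0311) and oxidative phosphorylation (adjusted p 0.00338 to 0.0196) were called lower, against adjusted p = 0.0601 and 0.138 with all libraries.

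The untreated lines differed at more genes than the treatment changed. PITX1, a homeobox gene (ENSG00000069011, chromosome 5, 135027734 to 135034757), had 408 CPM in MV411 DMSO and 0 counts in MOLM13 DMSO, at least 22600-fold higher. The axon guidance receptor gene UNC5C, the tumour suppressor gene CDKN2A (ENSG00000147889, chromosome 9, 21967752 to 21994873), PROSER1 and NDN also had 0 counts in MOLM13 DMSO and were at least 7040-fold, 4800-fold, 3660-fold and 1930-fold higher in MV411. In the other direction TNFRSF19 was at least 310-fold higher in MOLM13, and the carbonic anhydrase gene CA2, the natriuretic peptide receptor gene NPR3, SP9 and EGFL8 had log2 differences of -9.29 ± 0.12, -9.07 ± 0.43, -7.07 ± 0.63 and -6.50 ± 0.45 (SE) in MV411 against MOLM13. Without MV411 DMSO replicate 2, NPR3 had 0 counts in MV411 DMSO and was at least 639-fold lower there than in MOLM13 DMSO, and SP9 stood at -7.89. FLT3 differed by 0.23 (adjusted p = 1.42e-06), at 385 and 327 CPM. In all, 2757 genes were called higher and 2051 lower in MV411 DMSO against MOLM13 DMSO, and by adjusted p alone 5937 and 5686. These differences are between 2 cell lines and cannot be tied to any 1 property of them.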

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

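The tests chosen only after the result was seen were those of the summed histone counts and of the scaling of the libraries, and the reading of the test of poly(A) selection was also set after its values were seen. The results below stand out because the effect of SGI-7079 differed between the cell lines by the test of the difference, and each value is the log2 fold change in MV411 minus that in MOLM13. Only the named genes and the lists were screened. Many of these genes were named for a large change in 1 line or for the difference itself, which makes a difference likely. A negative value covers a smaller rise in MV411 (CFAP70, 3.02 in MOLM13 and 1.86 in MV411) as well as a deeper fall (CDC45, -1.63 and -3.29).

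Negative differences were found for CDC45 -1.66, CDC6 -1.63, DSCC1 -1.65, MCM10 -1.77, MCM4 -1.41, MCM6 -1.33, MYBL2 -1.50, RRM2 -1.04, SPC25 -1.11, TCF19 -1.54, EGR1 -1.77, ETV4 -1.94, FOS -1.62, FOSL1 -1.02, PIM1 -1.52 and GAS6 -1.22, and for CFAP70 -1.16, CSPG4 -1.99, DPEP2 -1.10, GAL -2.06, GLB1L2 -2.92, LINC01226 -1.26, PHGDH -1.29, SLC29A1 -1.62 and TRIM73 -1.17. FOSL1 came inside the fold threshold without MV411 DMSO replicate 3 or MV411 SGI-7079 replicate 3 (-0.98 to -0.94). CFAP70 lost its call without MV411 DMSO replicate 3 or MV411 SGI-7079 replicate 2 (adjusted p 0.0574 to 0.0618), and TRIM73 without MV411 DMSO replicate 3 (adjusted p = 0.0583).

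Positive differences were found for SLC7A11 3.67, CHAC1 2.35, LILRB3 3.76, PRAM1 2.12, FCGR2C 1.46 and DNASE2 1.86, and for CACNA2D4 1.51, CKB 2.98, IGF1 5.70, INHBA 1.21, LRG1 1.09, MYOM1 1.61, OAS2 1.07, SP9 2.89, STON1 2.31, TENT5A 1.19, UNCX 1.59 and ZC3H3 1.57. IGF1 was at 0.0355 CPM in MOLM13 DMSO, and its call was lost without MOLM13 DMSO replicate 3, which left 1 count in that group (adjusted p = 0.464). Without MOLM13 SGI-7079 replicate 1 that treated group had 0 counts and the difference was at least 6.14, and without replicate 2 or 3 it was 5.03 and 5.10. SP9 lost its call without MV411 DMSO replicate 3 or MV411 SGI-7079 replicate 1 or 3 (adjusted p 0.0508 to 0.061), and stood at 2.26 without MV411 DMSO replicate 1 and 3.64 without MV411 DMSO replicate 2. INHBA came inside the fold threshold without MOLM13 SGI-7079 replicate 1 (0.94) and reversed to -0.35 with limma on log2(FPKM + 1), with and without its filter (adjusted p = 0.00787 and 0.0182), LRG1 without MOLM13 DMSO replicate 3 or MOLM13 SGI-7079 replicate 2 (0.98 to 1.00), and OAS2 without MOLM13 DMSO replicate 1 or 2, MOLM13 SGI-7079 replicate 1 or 3, or MV411 DMSO replicate 1 or 2 (0.94 to 1.00).

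Among lists, the median differences were -1.15 for DNA replication, -0.69 for ERK targets, -0.67 for p53 targets, -0.47 for mitochondrial mRNAs, -0.46 for MYC targets, -0.41 for mitosis, -0.40 for ribosome biogenesis, -0.40 for cholesterol synthesis, -0.34 for STAT5 targets, -0.25 for the BCL2 family and -0.12 for ribosomal proteins. They were 0.84 for MHC class II, 0.21 for the interferon response, 0.14 for ATF4 targets and 0.09 for tRNA synthetases. With an estimated correlation the calls of ERK targets, mitochondrial mRNAs, STAT5 targets, the BCL2 family, ribosomal proteins, the interferon response, ATF4 targets and tRNA synthetases were lost (adjusted p 0.0562 to 0.52), and the other 7 held. The monocyte list was not called in the difference (median -0.15, 2 higher and 6 lower of 26, adjusted p = 0.274). The calls of ATF4 targets and tRNA synthetases were lost with single libraries left out, ATF4 targets without MOLM13 DMSO replicate 1, MV411 DMSO replicate 2 or MV411 SGI-7079 replicate 1 (0.04 to 0.09), and tRNA synthetases without any 1 of the 6 MOLM13 libraries, MV411 DMSO replicates 1 and 2 and MV411 SGI-7079 replicate 1 (-0.01 to 0.03).

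Other splits of the libraries were used to ask whether chance gives as many called genes. Of the 10 splits of the 6 libraries, 1 gave as many as the real one for MOLM13 (the real split itself, 2655 called, highest other 2), 1 for MV411 (3671, highest other 2) and 1 for the untreated lines (4808, highest other 0), and 10 splits are too few for a share under 0.05. For the difference between lines, 7 of 100 splits within lines gave as many called genes as the real 772, the real one included, with 2971 as the highest other, so by this share chance is not excluded. With 40 and 80 splits, tried before the number was fixed at 100, 2 and 4 gave as many. The 6 other splits were among 11 that kept the treatment groups of MV411 whole while mixing those of MOLM13. These 11 gave 295 to 2971 called genes, so not all of them reached the real count. They carry the treatment effect of MV411 into the difference, which is a structure of the samples, so the share cannot decide on chance. The 77 splits that mixed the groups of both lines gave 0 to 4 called genes.

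The first pattern is that DNA replication genes fell further in MV411. A generally stronger response of MV411 goes with part of it, since random lists matched on the MOLM13 fold changes had a median of -1.65 in MV411 against the list's -1.16 in MOLM13. Of 10000 such lists 0 had a median as low as -2.42, at percentile 0.0 (lowest -2.14). This argues against a stronger response as the whole cause, but less firmly than the percentile reads. The lists drew their genes independently, while replication genes move together (estimated correlation 0.088), so the spread of random medians is too narrow. The scaling is argued against because the list's median difference lay at -1.133 from that of the other genes (upper quartile -0.839), which a scaling of libraries leaves as it is, and a single library by a highest median difference of -1.145 over the 12 fits that leave out 1. What stays open is a difference between the cell lines, or between single cultures of them. The labels do not state that replicates were separate cultures, so leaving out 1 library does not test the latter. Also open is the hypothesis that replication genes in MV411 may respond more to the inhibitor, found and tested on the same data.

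The second pattern is that 7 of 11 replication-dependent histone genes rose in MOLM13 and 6 of 11 in MV411 while S-phase genes fell. The histone list was called in MOLM13, though not with an estimated correlation, and was not called in MV411. The summed CPM of 64 histone genes rose 5.32-fold in MOLM13 and 3.8-fold in MV411. Sharing of reads between copies would leave this sum unchanged if each shared read is counted once. How such reads were treated is not given in the sources used here, so the sum argues against sharing only under that condition. The test was also set after most listed members were seen to rise, which made a higher sum likely. Weaker poly(A) selection in treated libraries was tested on 60 snoRNA, scaRNA, 7SK and 7SL genes, whose medians were -0.32 and -0.67 (1 rose and 2 fell in MOLM13, 2 and 14 in MV411), below the bound set beforehand for no such effect. That bound does not settle the question, because most snoRNAs are made from introns and can follow their host genes. Chosen after its values were seen, RN7SK rose by 1.249 and 1.322 in MOLM13 and MV411. The entries of the 5.8S ribosomal RNA, also chosen afterwards, rose by 1.467 to 1.716 and by 1.93 to 2.055. Neither RNA is made from an intron. In MOLM13 RN7SK was the only 1 of the 60 genes that rose. Poly(A) selection and a change of histone mRNA in the cells therefore cannot be told apart here, as the rise in these RNAs goes with the treatment groups.

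The third pattern is that treated libraries held more detected genes. Depth is argued against, because after thinning all libraries to 52352252 counts the treated ones still held 1060 more genes with at least 10 counts in MOLM13 and 1301 more in MV411. Genomic DNA or other background reads were tested on 151 olfactory receptor genes, whose summed CPM was 1.35 times the control in MOLM13 and 1.43 times in MV411, between the bounds set for either outcome. Background reads, the weaker poly(A) selection left open above and a wider transcription in treated cells cannot be told apart from these values. The same holds for the excess of higher calls among genes of low abundance.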

How the results depend on the processing

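No test in this part was chosen after the result was seen. The depth of 52352252 to 61862017 counts limits genes of low count most. The simulated MOLM13 comparison changed far fewer genes than the data show, and used the adjusted p alone. In it 94.1% of 3-fold changes were found among planted genes with a mean of at least 100 counts, and 66% among all planted genes. DESeq2 kept 98.3%, 98.4%, 90.8% and 98.6% of the called genes in MOLM13, MV411, the difference and the untreated lines, and RLE scaling 99.1%, 99.5%, 99.1% and 99.4%. With single libraries left out, 81.9% to 96.9%, 82.3% to 92.3%, 78.8% to 82.0% and 89.9% to 98.0% were kept, and every count of called genes stayed within 1.5 times, except opposite calls in the lines (9 to 19, with 9 without MOLM13 SGI-7079 replicate 2). Over these fits 10468 of 10704 comparisons of named genes stayed on the same side of the threshold, 87 lost a call, 149 gained one and 0 reversed. Under the other alternatives 6159 of 6506 stayed, 275 lost a call, 68 gained one and 4 reversed. Of list comparisons 935 of 1008 stayed with a library left out, and 360 of 420 under the other alternatives.

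With no threshold on the fold, counts were 4971 higher and 5052 lower in MOLM13, 5830 and 5205 in MV411, 1898 and 2530 in the difference and 5937 and 5686 between untreated lines, with 3653 shared higher, 3970 shared lower and 314 opposite. With glmTreat they were 550 and 306, 781 and 729, 39 and 47, and 1772 higher between untreated lines. The first rule is looser and the second stricter by construction. With limma on log2(FPKM + 0.1) they were 1011 and 399, 1340 and 829, 227 lower in the difference, and 1585 and 990. With limma on log2(FPKM + 1) they were 271 and 245, 581 and 547, 128 and 87, and 810 and 597, and without its filter 266 and 245, 582 and 541, 118 and 77, and 811 and 599, and the cause was not tested. On that scale the differences of IGFBP2 and INHBA reversed to -0.84 and -0.35, with and without the filter, and the cause was not tested. The fit of each line alone gave 5 opposite calls, and the cause was not tested.

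With an estimated correlation, camera called 5 lists higher and 7 lower in MOLM13, 1 and 5 in MV411, and 1 and 6 in the difference. Fry, which does not compare a list with other genes, called 13 lists higher in MOLM13 and 10 in MV411, and gave the BCL2 family in MOLM13, at a median of -0.071, an upward direction (adjusted p = 0.00254). With all libraries, 6 lists were called higher in MV411 and 4 in the difference. With single libraries left out, 3 to 5 lists were called higher in MV411 (3 without MOLM13 DMSO replicate 1, 2 or 3 or MOLM13 SGI-7079 replicate 2 or 3) and 2 to 5 in the difference (2 without MOLM13 DMSO replicate 1, MV411 DMSO replicate 2 or MV411 SGI-7079 replicate 1). Without any 1 of the 6 MOLM13 libraries, MV411 DMSO replicates 1 and 2 and MV411 SGI-7079 replicate 1, the median fold change of all genes in MV411 was 0.03 to 0.056, against 0.114 with all libraries and 0.102 to 0.122 without the other 3. The median of all genes in the difference moved as well, from -0.014 to between -0.103 and -0.086, against -0.021 to -0.006 without the other 3, and the differences of tRNA synthetases (0.09) and ribosomal proteins (-0.12) are of a similar size to this move. Leaving out a MOLM13 library changes no MV411 count, so in those 6 fits the move came from refitting the filter, the scaling and the dispersion. MV411 calls lost without a MOLM13 library depend on that refit and not on other MV411 counts. Which step of the refit caused the move was not tested.

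Whether the replicate numbers pair the samples stays open. Same-numbered DMSO and SGI-7079 libraries had correlations of deviations of -0.017, 0.051 and 0.101 in MOLM13 and -0.007, 0.027 and 0.038 in MV411. With the replicate number as a block, 1759 and 727 genes were called higher and lower in MOLM13, 2168 and 1272 in MV411, 339 and 335 in the difference and 2223 and 1765 between untreated lines, and monocyte markers in MV411 had adjusted p = 0.0541. Not every library correlated best with its own number.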

Other observations

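The test of KEGG terms was chosen only after the result was seen, and the test of CDKN2A was not.

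Beyond the lists fixed beforehand, the called genes were tested for KEGG terms (Fisher's exact test, one-sided, Benjamini-Hochberg over 321 terms). Past an adjusted p of 0.05 were 21 terms for genes called higher and 11 for genes called lower in MOLM13, and 24 and 13 in MV411. The term with the smallest p among genes called higher was systemic lupus erythematosus, with 31 of 83 genes in MOLM13 (adjusted p = 1.63e-14) and 35 in MV411 (adjusted p = 7.67e-13). Neutrophil extracellular trap formation had 29 of 124 in each line (adjusted p = 5.33e-08 and 8.33e-05), and both terms hold histone genes. ECM-receptor interaction had 16 of 59 in MOLM13 and 12 in MV411 (adjusted p = 2.51e-05 and 0.0989), complement and coagulation 13 of 45 and 12 (adjusted p = 1.2e-04 and 0.013), hematopoietic cell lineage 15 of 64 and 22 (adjusted p = 3.06e-04 and 3.02e-06) and cell adhesion molecules 16 of 97 and 34 (adjusted p = 0.00832 and 5.74e-10). Terms named for other tissues passed as well. Neuroactive ligand-receptor interaction had 24 of 144 and 35 (adjusted p = 3.43e-04 and 4.91e-06), and olfactory transduction 6 of 39 and 10 (adjusted p = 0.187 and 0.0401). The background was not matched on abundance. Terms among higher calls may therefore reflect the excess of such calls among genes of low abundance. The term with the smallest p among genes called lower was the cell cycle, with 43 of 154 in MOLM13 and 63 in MV411 (adjusted p = 7.62e-20 and 6.51e-26). Genes called lower also included 13 of 54 of the Fanconi anemia pathway, a DNA crosslink repair route, in MOLM13 (adjusted p = 6.41e-05) and 25 in MV411 (adjusted p = 2.27e-11). Homologous recombination had 8 of 41 in MOLM13 and 19 in MV411 (adjusted p = 0.0214 and 1.37e-08), mismatch repair 6 of 23 and 14 (adjusted p = 0.0214 and 2.62e-08) and base excision repair 7 of 44 and 16 (adjusted p = 0.119 and 1.65e-05). The p53 signaling term had 10 of 69 called lower in MOLM13 and 17 in MV411 (adjusted p = 0.0435 and 0.00208), while the list of p53 targets was called higher in MOLM13. Many repair genes are also replication genes, so these terms are not independent of the replication list.

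CDKN2A, the gene of the p16 and ARF tumour suppressors, had 0 counts in all 6 MOLM13 libraries and 27228 in the 6 of MV411. A deleted segment of chromosome 9 in MOLM13 is a candidate explanation. It was tested on the neighbours CDKN2B and MTAP, which together had 11355 counts in MOLM13, all of them from MTAP, with CDKN2B at 0. CDKN2A-AS1 was also at 0, while CDKN2B-AS1, which overlaps the segment, had 536. A short deletion that spares MTAP and silencing of the genes at 0 cannot be told apart from RNA counts.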
